A study of Mus musculus with 2 samples.

How the data were processed

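Total RNA of R1-9 mouse embryonic stem (ES) cells was measured on 2 two-colour Agilent arrays of 60-base probes. Per the labels, the R1-9 RNA carried Cy3 on both arrays. The other dye, Cy5, carried a common reference: equal parts of RNA from 11 cultured mouse cell lines, mixed 2:1 with RNA of 129ES cells grown with LIF. Dyes were not swapped, so an effect of the dye on a probe cannot be separated from a difference between the samples. Both arrays lay on 1 slide and were read in 1 scan, so slide and scan could not be tested as batches.

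The scanner files hold spot intensity, that is, the mean signal and the median local background in each colour, as written by Agilent Feature Extraction 9.5.1.1 per the file headers. They also hold that program's log10 ratio of Cy5 over Cy3, its processed signals and its flags. The submitters' processing notes name Agilent Feature Extraction. The deposited value table gives log10 values for 25164 features. Each was found to equal log10 of the Cy3 processed signal minus log10 of the Cy5 processed signal plus the mean over both arrays of log10 Cy5, to within 0.000146. The columns of that table were not centred, and their medians were 2.36 and 2.36. Ratios in the text are R1-9 over reference, with the direction taken from the labelled dyes.

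The main values were computed from the mean and background signals in limma 3.58.1 under R 4.3.3. Background was corrected with normexp and an offset of 50, each array was normalized by loess with control spots at weight 0, and control spots and outlier-flagged spots were then left out. Spots of the same probe were averaged. A probe was tested if it was well above background in the same channel on both arrays, in either channel. An intercept was fitted per probe with lmFit and eBayes against a log2 ratio of 0. Tests were 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The treat function tested ratios beyond 3-fold. The labels do not say that the samples came from separate cultures, so p-values measure only the spread between these 2 arrays, which may be technical. The reference was treated as fixed. With 2 arrays, the residual variance of each probe has 1 degree of freedom, and the number of arrays limits the precision.

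The test, the samples, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The gene lists and the part of the rule that needs symbols could not be applied. The files do not pair the 42006 probe codes with gene names or positions, and 0 of the codes were found in the reference table of mouse genes. In place of the 10 highest and 10 lowest named genes, the 2 highest and 2 lowest probes are given by code. They were taken among called probes well above background in both channels on both arrays, with the same sign on each.

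Groups of probes defined by their own sequence replaced the gene lists. They were chosen with the files in hand but before any log ratio was computed for a group. Protein motifs were searched in the 3 reading frames of the probe strand, and RNA motifs as short matches on that strand. Of 23 groups, 14 had at least 5 tested probes and were tested. The groups were tested with camera at a preset correlation of 0.01, and each median was set against 10000 random lists matched on brightness and GC content.

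On array 2, 4 spots had a local background over 2 times the array's median, and array 1 had 0. The lowest background-subtracted Cy3 signal of array 2 was -11969.8. With these spots the background mean fitted by normexp on array 2 was -257 in Cy3 and -117 in Cy5, against -3.71 and -9.17 without them. On array 1 it was -3.29 and -11.4. The designed fit was kept as the main result. A second fit, called the repaired background below, estimated the background without the 4 spots and left them out. It was added after the planned settings had been compared.

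The fit was tested on simulated data made with the variance fitted to the real arrays and 4 spots of extreme background on array 2. For recovery, only probes with a mean background-subtracted Cy5 signal above 200 were changed and tested, so dimmer probes are not covered. The variance of the main fit already holds the effect of the 4 real spots, so the simulated ones add that effect again. With the variance of the main fit and 8000 of 19431 simulated probes changed, the designed background recovered 26.0% of 1.5-fold, 64.3% of 2-fold and 81.4% of 4-fold changes. The repaired background recovered 70.8%, 91.9% and 97.8% of the same changes. The SD between arrays was 0.57 in that simulation and 0.40 in the data. With 200 probes changed and that variance, 0 of the 66 probes changed 4-fold were called under either background. With the variance of the repaired fit and 200 changed probes, the repaired background recovered 98.5% of 1.5-fold and 2-fold changes and 100% of 4-fold changes. The designed background recovered 79.1%, 97.0% and 100% there. Of the calls, 7.04% were false with the repaired and 3.66% with the designed background. With 8000 changed probes and the variance of the repaired fit, the designed background recovered 92.4%, 99.0% and 100%, and the repaired background 100% of each. In 40 simulated groups of 16 probes raised by 1.2 on the log2 scale, camera gave an unadjusted p under 0.05 for 40. With an estimated correlation it did so for 0 of the 40, and in 40 unchanged groups the counts were 2 and 0.

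Alternatives changed the background correction, the offset, the normalization, the filter on dim probes, the variance model and the flags. Others took the scanner program's processed signals or the deposited table, or left out each array in turn. Also added were median centring on the repaired background, removal of the trend of log ratio on base composition, and the features of the deposited table alone. For probes well above background in 1 channel only, a lower bound of the fold was computed after loess and Aquantile scaling. The dim channel was set to the higher of its own signal and the lowest signal of any probe well above background on that array. These bounds are open to dye bias.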

Results

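R1-9 is a male mouse ES cell line. The cells were first grown on fibroblast feeders with LIF, the cytokine that keeps mouse ES cells undifferentiated, and then for 3 passages on gelatin without feeders. One group of 2 samples was measured, each on an array against the same reference RNA. The median spot signal of array 1 was 114 in the R1-9 channel and 189 in the reference channel, against local backgrounds of 46 and 46. On array 2 the signals were 115 and 178 over backgrounds of 47 and 47. The design gives a single comparison, that of R1-9 with a reference made up of 11 pooled cell lines and, for 1 part in 3, of another ES line.

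Most of the transcripts measured were present on both sides. Of 42006 probes, 27126 (64.6%) were well above background in R1-9 on both arrays and 27676 (65.9%) in the reference on both arrays. Of those, 25774 (61.4% of all probes) were measured on both sides. On both arrays, 865 probes were well above background in R1-9 and on neither in the reference, and 1310 showed the reverse. In both channels of both arrays, 11237 probes (26.8%) were not well above background, and 0 spots were saturated.

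Among probes in 1 channel only, those of the reference reached larger bounds. A difference of at least 2-fold was set for 40 of the R1-9 probes and 232 of the reference probes. The largest bounds were at least 4.97-fold for R1-9 and at least 34.2-fold for the reference. The repaired background gave 114 and 399, and the largest bounds were at least 8.02-fold and at least 69.3-fold. A bound is not a test. Of all 865 R1-9 and 1310 reference probes, limma's moderated test called 1 and 50 in that direction in the main fit. On the repaired background it called 802 and 1240.

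The R1-9 channel differed from the reference channel at a large share of the probes tested, in both directions. Without a dye swap, a call can be a difference between the samples or an effect of the dye on a probe. Of 28983 probes, 4385 were called higher in R1-9 and 5182 lower. Of these, 1924 were at least 2-fold higher and 2738 at least 2-fold lower. The extremes were wider on the low side: the mean log2 ratio ran from -8.36 to 4.11, a range of 327-fold lower to 17.3-fold higher. The highest 0.1% of ratios began at a log2 ratio of 3.40 and the lowest 0.1% ended at -5.21.

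These calls come from limma's moderated test at an adjusted p threshold of 0.05, and the lowest adjusted p was 0.0117. With the repaired background 10792 of 28981 probes were called higher and 11539 lower, with 2745 and 3843 at least 2-fold. All 9567 calls of the main fit were among them with the same direction. The split between higher and lower calls depends on the scaling. In the main fit 45.8% of calls were higher, and with each array centred on its median in place of loess 12.7% were. That centring, on all non-control spots of an array, moved the median log2 ratio of the probes tested from -0.02 to -0.44. The spots centred on include those of probes too dim to be tested. With the scanner program's signals 54.4% of calls were higher, and 54.8% with the deposited table, so that more calls were higher than lower. The deposited values come from the same signals for part of the probes, so these settings are not independent. On the repaired background, 48.3% of calls were higher with loess and 28.7% with median centring, which moved the median from -0.02 to -0.29.

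**Figure D1:**
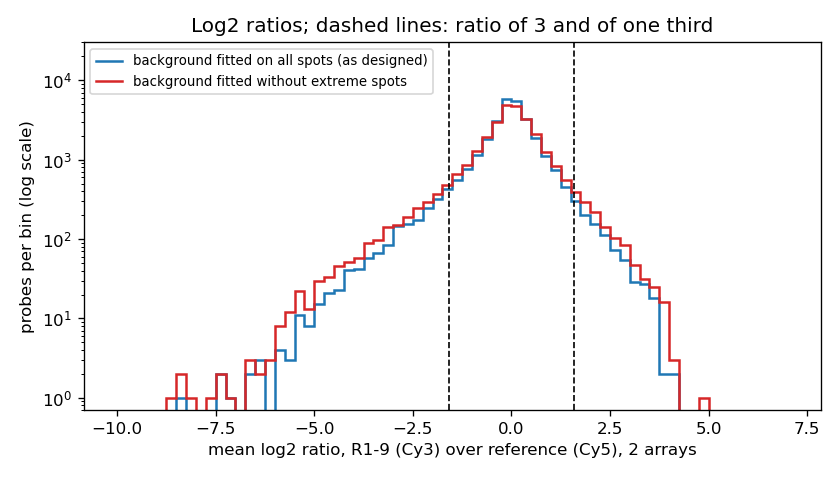
Number of probes (log scale) against the mean log2 ratio of R1-9 over reference on 2 arrays, for the background fitted on all spots and for the repaired background. Dashed lines mark 3-fold higher and 3-fold lower, and the low side runs to -8.36 where the high side ends at 4.11 in the main fit.

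The 2 highest and 2 lowest probes are given by code. Probe Z00057247-1 (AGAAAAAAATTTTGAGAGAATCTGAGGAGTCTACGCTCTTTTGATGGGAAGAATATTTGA) had a log2 ratio of 4.11 (SE 0.43, n = 2; limma adjusted p = 0.0186). Its arrays gave 4.84 and 3.39, and on the repaired background 4.84 and 4.67. It stood at 3.55 with median centring, 5.84 with plain subtraction and 6.29 with the scanner program's signals. Its signal was 1875 and 1750 in R1-9. In the reference it was only 99.4 and 103, over median local backgrounds of 46 and 47. Probe Z00026928-1 (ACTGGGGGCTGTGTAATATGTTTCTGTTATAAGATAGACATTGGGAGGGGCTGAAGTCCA) had a log2 ratio of 4.11 (SE 0.09, n = 2; limma adjusted p = 0.0117). Its signal was 13248 and 16814 in R1-9 against 1402 and 1483 in the reference, and its log2 ratio was 3.28 with median centring.

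The lowest was probe Z00070458-1 (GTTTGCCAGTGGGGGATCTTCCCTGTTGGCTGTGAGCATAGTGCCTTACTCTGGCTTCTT), at -8.36 (SE 0.26, n = 2; limma adjusted p = 0.0117). Its signal was 385 and 406 in R1-9 and 312986 and 290234 in the reference. Probe Z00075584-1 (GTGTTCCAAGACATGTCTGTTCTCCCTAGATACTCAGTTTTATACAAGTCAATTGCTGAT) stood at -7.47 (SE 0.60, n = 2; limma adjusted p = 0.0143), with arrays at -8.49 and -6.45. Its signal was only 76.3 and 82.8 in R1-9, over median local backgrounds of 46 and 47, against 55526 and 51299 in the reference. The probe stood at -9.65 with plain subtraction and -9.91 with the scanner program's signals, so the size of its ratio depended on the background correction. Probe Z00070458-1 stood at -8.89 and -8.88 there, so which of the probes was lowest depended on the background correction. On the repaired background the lowest probes Z00070458-1 and Z00075584-1 stood at -8.70 and -8.39. The gene of each probe is not named in the files.

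Because 1 part in 3 of the reference was ES cell RNA, a transcript at the same level in both ES lines and in no other cell line would have a ratio of 3, a log2 ratio of 1.58. A mean ratio above that value was measured for 870 probes, and 1714 probes were more than 3-fold lower in R1-9. On array 1, 1251 probes lay above it and on array 2, 663 did. Of these, 645 lay above it on both. On the repaired background 1251 probes lay above it on array 1, 1212 on array 2 and 1134 on both. Limma's treat test called 0 probes beyond 3-fold higher and 0 beyond 3-fold lower in the main fit, where its lowest adjusted p was 0.0756 and 488 probes higher and 1035 lower had an unadjusted p under 0.05. Treat on the repaired background called 887 higher and 1796 lower, and 1228 probes had a mean ratio above 3. With median centring in the main fit, 323 probes had a mean ratio above 3.

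Probes that encode the peptide joining neighbouring C2H2 zinc fingers, the DNA-binding units of a large family of transcription factors, had a higher median in R1-9, though whether they were called as a group depended on the test. Of 16 such probes tested, 8 were called higher and 0 lower, and 13 had a ratio above 1 on both arrays. Adjusted over the list alone, 9 were higher and 2 lower. Their median log2 ratio was 1.21 (SD 1.12 over probes), against -0.42 to 0.34 for 95% of matched random lists. Probe Z00060976-1 (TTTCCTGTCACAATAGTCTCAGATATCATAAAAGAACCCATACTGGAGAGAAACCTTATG) was the highest of them at 2.95, and probe Z00036554-1 the lowest at -0.83 (limma adjusted p = 0.0523). Both were singled out after their values were seen. The repaired background gave 13 calls higher and 2 lower, with a median of 1.34.

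Camera called this group alone among 14 (adjusted p = 0.00863, and 0.00788 on the repaired background). In the deposited table, which holds 10 of the 16 probes, it called 0 groups, with the linker median at 1.55 (SD 1.25, mean 1.11) and an adjusted p of 0.304. The main values of the same 10 probes, tested among the features of that table alone, gave a median of 1.21 (SD 0.95, mean 0.78, against 1.04 over 16) and 0.298. With an estimated correlation the adjusted p was 0.861, and 0.490 on the repaired background. By fry, which tests the group by itself, the adjusted p was 0.105 in the main fit and 0.0364 on the repaired background. On that background fry called 12 of the 14 groups, so its call does not set the linker group apart. Among the 12 were the core histone group (fry adjusted p = 0.0338) and a control, the reverse complement of the let-7 site (0.0346). With median centring the group median was 0.52 where that of all probes tested was -0.44.

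Probes with core histone peptides did not stand apart from other probes. Of 10 tested, 1 was called higher and 4 lower, with a median of -0.05 (camera adjusted p = 0.695), and with the repaired background 3 and 5, with a median of -0.06. Of 161 probes with a 7-base match to the shared seed of the miR-290 and miR-302 microRNAs, which are abundant in mouse ES cells, 17 were called higher and 40 lower, with a median of -0.13 (repaired background: 49, 80 and -0.17). Of 116 with a match to the seed of let-7, a microRNA of differentiated cells, 22 were called higher and 11 lower, with a median of 0.08 (repaired background: 53, 30 and 0.09). Of 47 with an AU-rich nonamer, a sequence found in short-lived mRNAs, 2 were called higher and 17 lower, with a median of -0.28 (repaired background: 14, 26 and -0.37). Camera called none of these 3 groups (adjusted p = 0.333 for each, and 0.283 to 0.339 on the repaired background).

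The other groups tested were matches to the seeds of miR-17, miR-16, miR-1, miR-122 and miR-124, Pumilio sites, the polyadenylation signal and the reverse complements of the miR-290 and let-7 sites. Their medians lay between -0.11 and 0.07, or -0.13 and 0.10 on the repaired background, and camera called none of them. In the main fit the lowest camera adjusted p among them was 0.409, for the reverse complement of the miR-290 site.

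**Figure D2:**
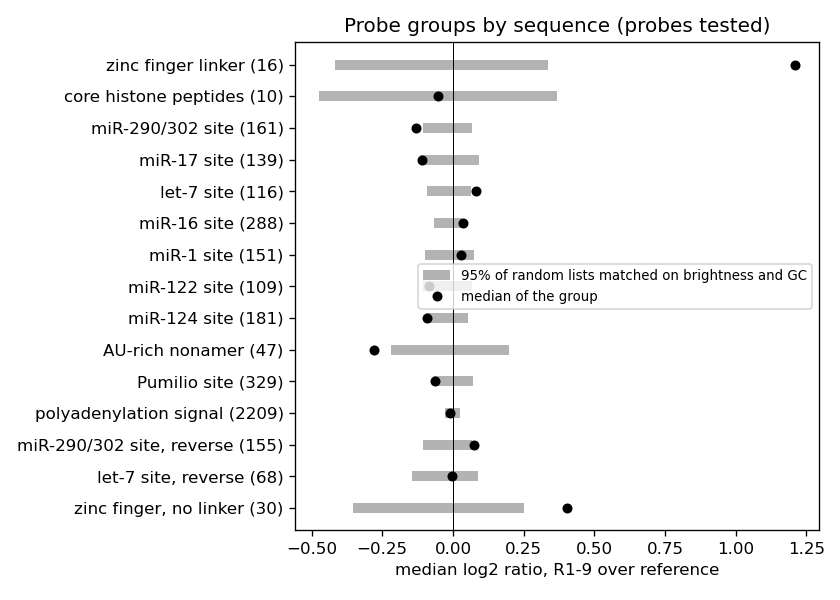
Median log2 ratio of R1-9 over reference (points) for groups of probes defined by sequence in the main fit, with the number of probes tested in brackets. Grey bars hold 95% of the medians of random lists matched on brightness and GC content, and the zinc finger linker group stands at 1.21 above a bar that ends at 0.34.

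The log2 ratios of the arrays were close across probes, and closer on the repaired background. Across the probes tested, which are not independent replicates, Pearson's r was 0.952 and Spearman's rho 0.950. The SD of the difference between arrays was 0.40. These values were 0.988, 0.968 and 0.17 on the repaired background. The sign was the same on both arrays for 91.1% of probes. For 19 pairs of probe codes with the same sequence, the robust SD of the difference within an array was 0.06, and that between arrays 0.35. They were, on the repaired background, 0.10 and 0.15.

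**Figure D3:**
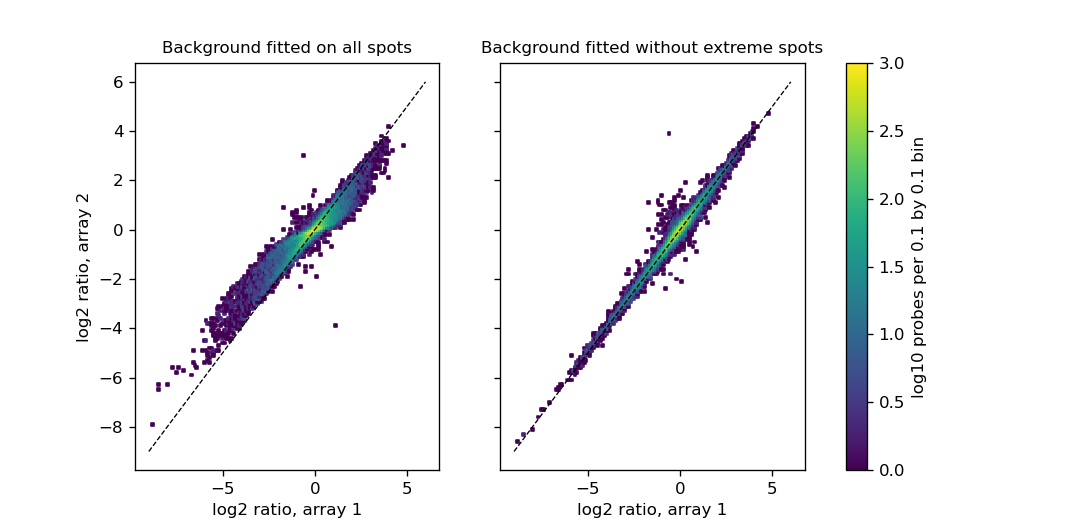
Log2 ratio of R1-9 over reference on array 2 against array 1, with colour giving log10 of the number of probes per bin and the dashed line marking equal values. With the background fitted on all spots, ratios on array 2 are drawn toward 0, and r is 0.952. On the repaired background r is 0.988.

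Levels of R1-9 RNA differed more between arrays than levels of the reference, which was the same RNA on each. After loess and Aquantile scaling, the robust SD of the difference between arrays was 0.22 in Cy3 and 0.12 in Cy5, a ratio of 1.88 over 25774 probes measured in both channels. The ratio was 1.50 on the repaired background and 1.23 with each channel scaled by quantiles. With that scaling it was 0.953 among the dimmest of 3 equal sets of probes. Quantile scaling on the repaired background gave 1.40 over all probes and 1.18 among the dimmest. The dyes differ between these channels too, so the ratio does not separate a difference between the ES samples from the dye.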

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

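A class of control spots that the array design names EQC, which no comparison used, was brighter than the negative control spots. The test was chosen after the control spots had been seen. On average over both arrays and channels, 26.9% of its spots were well above background. On array 1, 10 of 40 were so in Cy3 and 11 of 40 in Cy5, against 3 of 153 negative controls in each. On array 2, 11 of 40 were in each channel, against 5 and 6 of 153. Fisher's exact test (one-sided, adjusted over 20 tests of 5 control classes) gave adjusted p-values of 4.03e-05 to 0.000212. That test counts every spot as independent, and copies of the same probe were not told apart. Its p-values therefore describe spots, not distinct probes. Both channels of an array read the same spots, so the 20 tests are not independent of each other. What the EQC spots carry is not given in the sources used here, and no explanation was tested. Another class, named DCP, passed on array 1 in both channels (5 of 36 spots, adjusted p = 0.0235 in each) and not on array 2 (3 of 36, adjusted p = 0.357 and 0.425). The spike-in class named E1A did not pass that test on either array, with 10 to 18 of 320 spots well above background, so it gave no check of the direction of the ratios.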

How the results depend on the processing

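The repaired background, its median centring, the base composition setting, the features of the deposited table alone and all settings of the sequence groups were chosen after seeing the data. Counts are given as higher and lower, for calls (4385 and 5182 in the main fit), calls of at least 2-fold (1924 and 2738), treat beyond 3-fold (0 and 0) and mean ratios beyond 3-fold (870 and 1714). Without background correction calls were 10887 and 11648, and treat gave 964 and 1859. With plain subtraction the counts were 10066 and 10860, 4109 and 5367, 1395 and 2484, and 2189 and 3432. With the scanner program's signals they were 11479 and 9604, 5007 and 5159, 1977 and 2639, and 2918 and 3545. The 1-channel bounds of at least 2-fold then numbered 454 for R1-9 and 793 for the reference, against 40 and 232. With an offset of 16, calls were 2446 and 3052. Median centring gave 1518 and 10428, 958 and 7638, 52 and 1364, and 323 and 3563. The deposited table gave 7633 and 6294, 3309 and 3380, 1381 and 1840, and 1959 and 2361, and 0 sequence groups by camera, against 1. It was tested on 18128 probes, 10 of them in the linker group, whose median was 1.55 (SD 1.25) against 1.21 (SD 1.12) over 16. Probes well above background in both channels gave 79 and 125 by treat.

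The repaired background gave 10792 and 11539 calls, 887 and 1796 by treat, bounds for 114 and 399 probes, and an SD between arrays of 0.17 in place of 0.40. With median centring as well, it gave 6751 and 16742 calls, 5900 at least 2-fold lower, 498 and 2475 by treat, and 3093 mean ratios more than 3-fold lower. Quantile scaling moved the Cy3 to Cy5 spread from 1.88 to 1.23, and to 1.40 from 1.50 on the repaired background. Camera with an estimated correlation, fry, and the features of the deposited table alone each called 0 sequence groups, though fry called 12 of 14 on the repaired background. Simulated groups raised by 1.2 also gave 0 of 40 with the estimated correlation. For the repaired background the fitted background mean shows the cause of the change. For the other settings the cause was not tested.

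Of the values compared, 57 moved further than 1.5 times from the main value and another 89 stayed within it. Some of the 89 could not move, since the variance model leaves the mean ratios, and so the counts of 870 and 1714, as they were. The values compared are counts, correlations and spreads, which cannot change sign. The order of higher and lower calls, 4385 and 5182 in the main fit, did turn round in some settings. It did so with the scanner program's signals (11479 and 9604) and the deposited table (7633 and 6294). Leaving out an array left 1 array, hence no test: probes with a mean ratio above 3 then numbered 663 to 1251, and those more than 3-fold lower 1281 to 2137. The 4 named probes kept their direction in all settings in which they had a value. They were picked for extreme ratios with the same sign on both arrays, so this says little about other probes. The gene list tests and the mean over a gene's probes were not run, since no gene names were held. No paired analysis was possible because there is 1 group. Of the 9661 dimmest probes, 80 were called in the main fit, where their robust SD between arrays was 0.33, and 6521 on the repaired background, where it was 0.13, as for the brightest. Probes not well above background in a channel have only a bound there.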

Other observations

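Chosen only after the result was seen were the tests on the repaired background, on the low tail and on all 7-mers, the base composition test of the zinc finger probes, and the random lists for linker probes that share no long run. The intervals on percentages, and the weight given to the reverse complement control, to the scaling test and to the small size of the base composition trend, were also added then.

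Zinc finger probes outside the linker group had a median above the range of 95% of matched random lists in most settings. A further 30 tested probes encode part of a C2H2 finger, from its phenylalanine to its paired histidines, without the linker peptide. Of these, 8 were called higher and 1 lower, and on the repaired background 18 and 3. Their median log2 ratio was 0.40 (SD 0.74 over probes), against -0.35 to 0.25 for 95% of matched random lists. It was 0.62 on array 1 and 0.22 on array 2, where the lists ran from -0.24 to 0.15. With no filter on dim probes it was 0.18 over 37 probes, against -0.14 to 0.09. With median centring it was -0.01, where the median of all probes tested was -0.44. In the deposited table it was 0.50 over 19 probes, inside its lists' range of -0.62 to 0.73, and the main values of the features of that table gave 0.29, also inside theirs, -0.51 to 0.34.

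A candidate explanation for the linker group is that transcripts of zinc finger genes were at a higher level in R1-9 than in the reference. Its test, written before the values of the 30 other finger probes were seen, placed their median at percentile 99.86 of matched lists. That percentile meets the prediction but leaves the explanation open. Among the sequence groups 6 of 14, a control among them, lay outside 95% of their lists, as did 5 of 40 unchanged simulated groups, and the finger probes can belong to the same genes as the linker probes. Base composition was not decided: the linker median without its trend was 0.984 of its value with it, but that trend explains 0.0601% of the variance. Probes with an identical run of 30 or more bases are argued against as the whole cause: 12.5% of the linker probes, 2 of 16, shared one with another. The other 14 had a median of 0.86, with 6 called higher and 0 lower, against -0.44 to 0.35 for 95% of matched random lists. The count took identical runs only, so it cannot decide on probes that are alike but for single bases. Probe Z00060872-1, with an identical run of 25 bases, is among those 14.

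Mean ratios above 3 go beyond what the stated mixing allows for a transcript at the same level in both ES lines. In the main fit, 51.6% of the probes above 3 on array 1 were above it on array 2 (95% Wilson interval 48.8 to 54.3). That share cannot decide on noise, since only 663 probes lay above 3 on array 2, against 1251 on array 1. Of those 663, 645 lay above 3 on array 1 too. That count cannot decide on noise either. Ratios on array 2 were smaller in size in this fit, so a probe above 3 there would tend to lie above it on array 1. Scaling stays undecided: 37.1% stayed above 3 with median centring, but a downward shift lowers this count whatever the cause. On the repaired background 90.6% of those above 3 on array 1 were above it on array 2, which argues against noise there, and 59.3% stayed with median centring, which argues against a shift of that size as the whole cause there. Removing the base composition trend left 99.2% above 3, and 98.5% on the repaired background, but that trend is too small for the test to decide. A lower level in 129ES than in R1-9 cells and a dye effect of single probes may both contribute, and no biological explanation was tested.

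Ratios reached further below 1 than above it. On the repaired background, 2 probes bright in R1-9 had a log2 ratio above 4, and 155 bright in the reference had one below -4. A hard limit at 3-fold set by ES cell RNA in the reference is argued against, since on that background the highest 0.1% of the ratios began 2.05 above it on the log2 scale. That RNA may still shorten the high side for transcripts shared by both ES lines, which the single reference leaves untested.

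A microRNA hypothesis, written before the groups' ratios were computed, was that let-7 targets are higher and targets of the miR-290 and miR-302 seed (the miR-290 site) lower in R1-9. The let-7 group's median lay at percentile 99.1 of matched random lists and the miR-290 group's at 0.80. The AU-rich group, expected to differ in either direction, lay at 0.72. These percentiles meet the predictions, but 6 of 14 groups lay outside 95% of their random lists, among them miR-16 (98.4) and the reverse complement of the miR-290 site (98.2), a control. The reverse complement of the let-7 site, the other control, lay inside at 65.5, and at 58.8 on the repaired background. With so many groups outside their lists, the percentiles leave the hypothesis open. Ranked among the 10949 7-mers found in at least 50 tested probes, the let-7 site lay at percentile 98.2, the miR-290 site at 0.288, the miR-16 site at 98.5, and the reverse complements of the miR-290 and let-7 sites at 96.4 and 37.4. These ranks use the same ratios and add no independent evidence.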
